A study of Mus musculus with 16 samples.

How the data were processed

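RNA of cultured mouse hepatocytes was hybridised as biotin-labelled cRNA to Illumina bead arrays, 16 arrays in 8 groups of 2, set by virus, treatment and time. Each deposited intensity in the table used here is the summary brightness of a probe's beads on a linear scale, summarised in GenomeStudio per the submitters' processing notes, with the version and settings not given in the sources used here. That table is called non-normalized, and its column medians differ between arrays. The p-value beside each intensity is a detection p of that probe on that array, per the file headers. A further table of deposited intensities, on the linear scale, served as an alternative. Its columns share nearly the same median and upper quartile but not the same maximum, so it had been normalized between arrays, by a method not given in the sources used here. Its columns were tied to groups by the sample names they carry. Arrays are named by group and by the letter A or B of the table's columns. Groups came from the sample titles, where GFP marks the control virus and shHDAC45 stands here for the shRNA virus.

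The intensities were background-corrected through the detection p-values, offset by 16, quantile-normalized and taken to log2 (neqc in limma 3.58.1 under R 4.3.3). Of 24613 probes, 20984 named 1 gene in the platform annotation, 1 named several and 3628 none. Symbols of 20968 probes were looked up through Entrez identifiers in a RefSeq gene table of the assembly GRCm38.p6, used for names only, and 16 kept the annotation's symbol; 0 symbols changed. Probes with a detection p under 0.01 on at least 2 arrays numbered 10439, of which 9308 named 1 gene. Of several probes of a gene, as for 1293 genes, the brightest by mean log2 signal was used, which left 7746 genes; other probes are mentioned where their call differs. Background lowers the fold changes of dim genes, and quantile normalization forces a common distribution on all arrays.

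One limma model of 8 group means over the 16 arrays gave 13 contrasts with moderated two-sided tests (8 residual and 4.6 prior degrees of freedom), Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. The contrasts were forskolin against DMSO per virus and time, knockdown against control per condition and averaged, and the interactions of treatment with time and with virus. A gene was taken as below background in a group where none of its probes was detected on any array of that group. The bound "at least N-fold" then sets the bright group's mean over its arrays against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal, in normalized log2 values. No fold is given where that bound is under 1 or both groups lie below background.

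Gene lists covered glucose, lipid and amino acid metabolism, signalling and stress responses, deacetylases, and markers of liver cell types. Of 27 lists, 1 had fewer than 5 measured genes and was not tested. Each was tested with limma's camera (preset correlation 0.01) in 5 contrasts, 130 tests adjusted together, and again with an estimated correlation. The size of the forskolin response in knockdown relative to control cells was the slope through the origin over genes called by the mean effect of both viruses, tested with limma's fry on the interaction and adjusted over the 2 times. The genes named were the 8 largest rises and 8 largest falls of a contrast among genes past the test whose arrays did not overlap between the groups. For the averaged knockdown effect the sign had to be the same in all 4 conditions, and interactions had no such condition. Also named were the targets, Hdac7, a fixed set of gluconeogenic and insulin-regulated genes, and up to 4 members of a described list with the smallest p. Only part of these are named for the knockdown contrasts. Irs2, of the fixed set, had no named probe.

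Groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Alternatives were no background correction (offset 50), median scaling, the authors' normalized values, other filters on dim probes, all probes, only the compared arrays, another variance prior, the replicate letter as a term, and leaving out each array, where the lone array left in a group is assumed to vary like the other groups. An orthogonal slope and the use of the DMSO arrays of the other time were added after seeing the data. The model fit was tested on simulated log2 values for forskolin against DMSO in control cells at 2 h. These held 7746 genes, of which 50 were changed at each size. Of those, 32% of genes changed by 0.5 on the log2 scale were recovered, 94% of those changed by 1, 98% by 2 and 100% by 3. Of the calls, 9 of 171 were false. The simulated noise was independent between genes and arrays, and fewer genes changed than passed in any contrast of the data. Background correction, normalization, filters and probe choice were not part of that test. Probes naming no single gene entered no comparison.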

Results

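Gene expression was measured in primary hepatocytes, the metabolic cells of the liver taken into culture, from C57BL/6 mice aged 6 to 8 weeks. The cells had been infected with 1 of 2 adenoviruses. The control virus is called GFP in the sample titles and shGFP in the design text, and the other carried shRNA against Hdac4 and Hdac5. Hdac4, Hdac5 and Hdac7 are class IIa histone deacetylases, which move between cytoplasm and nucleus and act together with transcription factors. Cells of both kinds then received forskolin, an activator of adenylyl cyclase that raises cAMP as glucagon does, or its solvent DMSO, for 2 h or 4 h. The title of the series puts the question as the part these deacetylases play in the liver's production of glucose. The 8 groups held 2 arrays each, 16 in all, and every p-value below rests on that number, which limits the precision. The sources used here do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Each array gave a signal for 24613 probes, with a median signal of 103.2 to 117 and 8455 to 10082 probes (34.4% to 41.0%) above background. Of the genes, 7746 were tested. Arrays of a group correlated at 0.992 to 0.994 across genes and arrays of different groups at 0.886 to 0.986, and the best match of each of the 16 arrays was the other array of its group. The first principal component, with 55.0% of the variance, separated the viruses.

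Hdac5 was strongly and Hdac4 moderately lower in the cells that received shRNA against them. Hdac5 (probe ILMN_2659160) averaged 9.57 on the log2 scale over the 8 control arrays and 6.07 over the 8 knockdown arrays, a difference of -3.50 (SE 0.064, limma adjusted p = 1.6e-13). The lowest control array, at 9.02, lay above the highest knockdown array, at 6.73. Its other probe (ILMN_1213290) was above background on 6 control arrays and 0 knockdown arrays. Under DMSO no knockdown array had Hdac5 above background, so that its level was at least 6.59-fold lower at 2 h and at least 6.55-fold lower at 4 h. Under forskolin it was 11.5-fold lower at 2 h and 13.3-fold lower at 4 h, where 1 of the 2 knockdown arrays was above background. Hdac4 (ILMN_1219682) differed by -1.49 (SE 0.10, adjusted p = 2e-08) and was above background on 8 control and 4 knockdown arrays. Its lowest control array, at 7.40, lay above its highest knockdown array, at 6.99. In single conditions Hdac4 was at least 2.00-fold lower under DMSO at 2 h, and its log2 differences were -1.38 under DMSO at 4 h, -1.34 under forskolin at 2 h and -1.69 under forskolin at 4 h. Under DMSO at 4 h and forskolin at 2 h 1 of the 2 knockdown arrays had Hdac4 above background. The averaged differences depend on the background level, since 2 knockdown groups for Hdac5 and 1 for Hdac4 lay below it. Hdac7, which the shRNA was not directed against, was also lower on average over the 4 conditions, by -0.72 (SE 0.060, adjusted p = 1.6e-07), but did not differ by the test under forskolin at 4 h (0.06, adjusted p = 0.67).

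**Figure D1:**
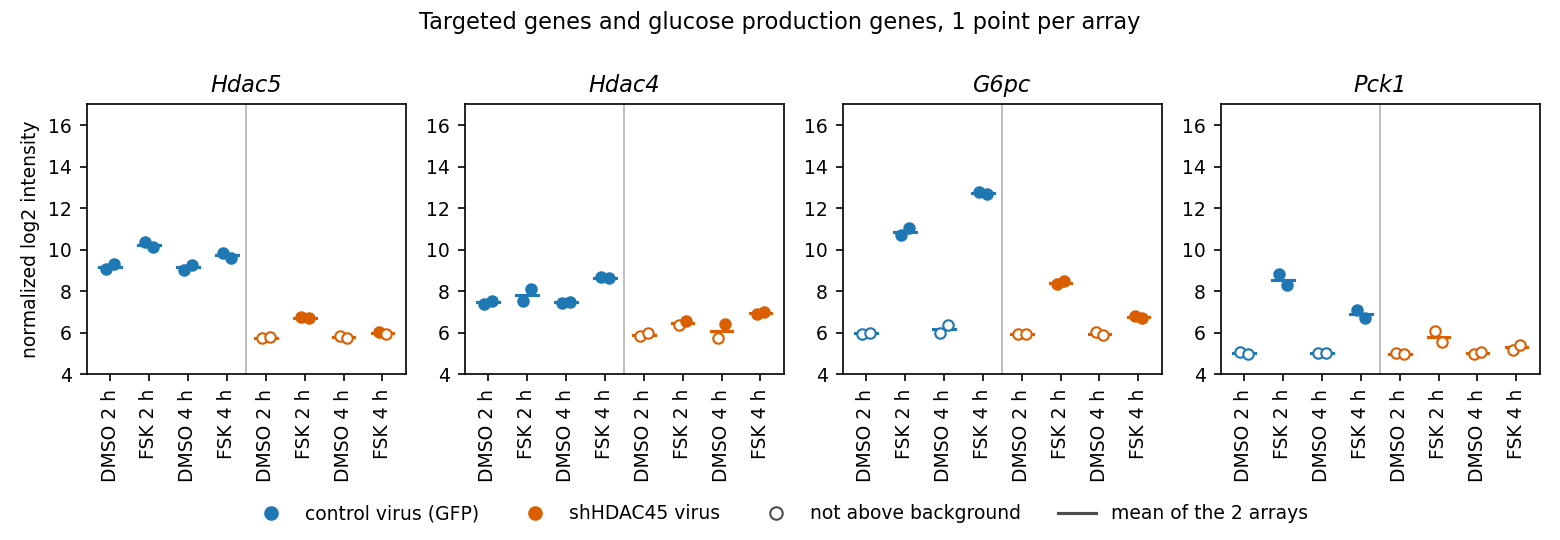
Log2 normalized signal of Hdac5, Hdac4, G6pc and Pck1 on each of the 16 arrays, by virus, treatment and time, with filled points above background and open points below it. G6pc averaged 12.75 in control cells after 4 h of forskolin and 6.76 in knockdown cells.

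After 2 h of forskolin in control cells, G6pc, which encodes the catalytic subunit of glucose-6-phosphatase and the last step of glucose production, rose from below background to a level at least 21.5-fold higher (log2 10.87 in the forskolin group, SD 0.24, adjusted p = 4.8e-11). Pck1, the enzyme that makes phosphoenolpyruvate from oxaloacetate, rose at least 4.33-fold (adjusted p = 2.8e-08), Ppargc1a, a transcriptional coactivator, at least 3.60-fold (adjusted p = 2.2e-08) and Igfbp1, a secreted binding protein of insulin-like growth factors, at least 1.63-fold (adjusted p = 0.00051). The nuclear receptor Nr4a2 rose at least 16.1-fold and the kinase Sik1 at least 11.1-fold. In the opposite direction Cxcl5 was at least 50.2-fold lower and Cxcl1, another neutrophil-attracting chemokine, fell by 7.02 on the log2 scale (SE 0.12, adjusted p = 5.5e-13). Other large rises were those of the transcriptional repressor Hey1, at least 25.4-fold, the ubiquitin protease Usp2, at least 4.75-fold, Klf4 (log2 difference 4.03, SE 0.16), the mitochondrial carrier Slc25a25 (3.94, SE 0.11) and the kinase Sgk1 (3.90, SE 0.11). The other large falls were in Tnfaip3, a feedback inhibitor of NF-kB, at least 20.1-fold, Ccn1, at least 8.28-fold, the chemokines Ccl4, at least 6.08-fold, and Cxcl2, at least 5.91-fold, Vnn3 (-4.67, SE 0.12) and Ccl7 (-4.62, SE 0.11). Hdac5 itself rose by 1.06 (SE 0.13, adjusted p = 5.9e-05). Hdac4 (0.33, adjusted p = 0.28), Hdac7 (-0.16, adjusted p = 0.40) and the gluconeogenic enzymes Fbp1 (-0.26, adjusted p = 0.21) and Pcx (below background under forskolin, at least 1.22-fold lower, adjusted p = 0.14) did not pass the test. Pcx passed it when fitted on the compared arrays alone (adjusted p = 0.033) or without either of the GFP forskolin 4 h arrays (adjusted p = 0.039), the range over all alternatives being 0.033 to 0.98. In all, 1651 genes passed the test, 818 higher and 833 lower, with a median SE of 0.13. That count fell to 1041 without GFP DMSO 2 h array A and to 1087 with only the compared arrays in the fit.

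Of 16 measured CREB-linked early genes, 13 rose and 0 fell after 2 h in control cells, 13 also adjusted over the list alone (median 2.20, or 1.85 with genes below background at their bounds; adjusted p = 9.9e-17). Crem, a cAMP-inducible repressor, rose by 3.42 (SE 0.14), and Egr1 (-0.29, adjusted p = 0.21) did not pass. Among 17 FOXO-linked genes 8 rose and 3 fell, with 8 and 4 adjusted over the list alone (median 0.19, adjusted p = 0.035), but adjusted p = 0.15 with an estimated correlation. This list shares G6pc and Pck1 with the gluconeogenic list and Ppargc1a with the CREB list. Of 11 class IIa deacetylases and partners 4 rose, Sik1 and Hdac5 among them, and 0 fell (median 0.33, adjusted p = 0.0081), but adjusted p = 0.18 with an estimated correlation. Of 11 circadian clock genes 4 rose and 0 fell (adjusted p = 0.043), also with adjusted p = 0.18 with an estimated correlation. For both lists the 4 genes also passed adjusted over the list alone. Of 10 gluconeogenic enzymes 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.28), and the list's median, -0.02, and its mean, 0.77, had opposite signs, the test pointing up.

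The acute phase and NF-kB list fell in control cells at 2 h, with 18 of 23 measured genes lower and 1 higher, 19 and 1 adjusted over the list alone (median -1.66, adjusted p = 9.3e-18). It is called the NF-kB list below, and its members NF-kB genes, although it also holds acute phase genes such as Crp and Saa3. Of 14 interferon response genes 6 fell and 0 rose, 7 and 0 adjusted over the list alone (median -0.41, adjusted p = 1e-04), including the transcription factor Irf1 (-1.68, SE 0.15) and the GTPase Gbp3 (-1.37, SE 0.13). Of 16 hepatocyte genes 8 rose and 0 fell, 8 also adjusted over the list alone (adjusted p = 0.00077), but adjusted p = 0.059 with an estimated correlation. Among them were the P450 gene Cyp2c37 (1.57, SE 0.11) and the liver transcription factors Foxa3 (1.31, SE 0.098) and Hnf4a (1.11, SE 0.12). Of 18 cell cycle genes 5 fell, 7 adjusted over the list alone, and 0 rose (median -0.33, adjusted p = 0.013), but adjusted p = 0.086 with an estimated correlation. The DMSO arrays themselves differed between the times: from 2 h to 4 h in control cells 18 of the 23 NF-kB genes fell (median -1.40). Against the DMSO arrays of 4 h, an alternative added after seeing the data, the calls ended for the NF-kB list (3 higher, 6 lower, median 0.15 with the test pointing down, adjusted p = 0.98), the interferon list (0.43), the hepatocyte list (0.39), the cell cycle list (0.083) and the clock list (0.050). The CREB list kept its direction (3.6e-20). The endothelial (0.0064), amino acid (0.014) and cholesterol synthesis (0.025) lists then passed, upward. In that comparison Cxcl5 (adjusted p = 0.94) and Cxcl2 (adjusted p = 0.68) lay below background in both groups and lost their calls. Vnn3 (-0.37, adjusted p = 0.052), Gbp3 (-0.32, adjusted p = 0.10) and Cyp2c37 (0.06, adjusted p = 0.76) lost theirs. Each of these 5 genes passed under every other alternative run, with adjusted p up to 0.0012 for Gbp3. With the 4 h DMSO arrays Hdac7 was lower (-0.61, adjusted p = 0.0036, range 0.0036 to 0.64) and Fbp1 higher (0.53, adjusted p = 0.019, range 0.019 to 0.49).

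**Figure D2:**
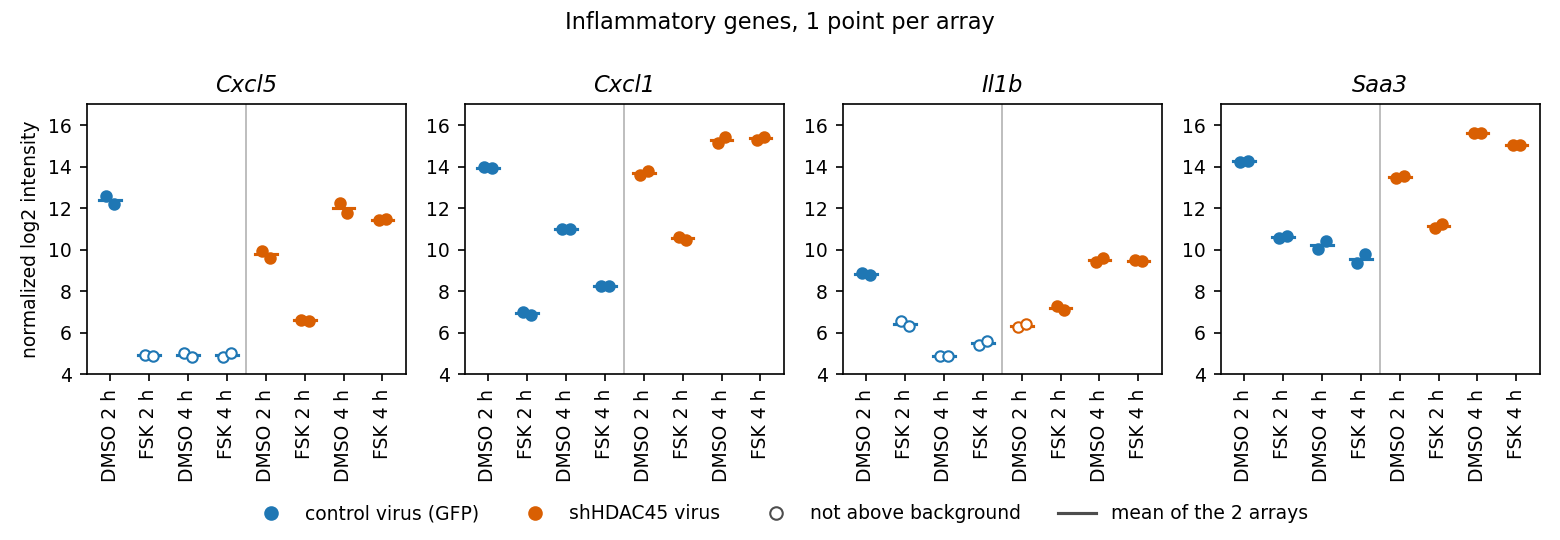
Log2 normalized signal of Cxcl5, Cxcl1, Il1b and Saa3 on each of the 16 arrays, by virus, treatment and time, with filled points above background and open points below it. In control cells under DMSO the signal was lower at 4 h than at 2 h (log2 difference -2.98 for Cxcl1 and -4.05 for Saa3).

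After 4 h of forskolin in control cells, G6pc stood at least 69.1-fold above DMSO (adjusted p = 1.1e-11), and Fbp1, the fructose-bisphosphatase of gluconeogenesis, rose by 2.12 (SE 0.14, adjusted p = 1.4e-07). Ppargc1a was at least 3.58-fold higher and Pck1 at least 1.21-fold higher (adjusted p = 3.8e-08 and 1e-05). Etnppl rose at least 11.6-fold, the glycine methyltransferase Gnmt at least 5.24-fold, and the alcohol dehydrogenases Adh1 (log2 4.29, SE 0.15) and Adh7 (at least 4.46-fold). So did the cationic amino acid transporter Slc7a2 (3.17, SE 0.12). The oxygen-sensing prolyl hydroxylase Egln3 (5.15, SE 0.12), the steroid hydroxylase Cyp17a1 (at least 11.9-fold) and Mmd2 (at least 12.4-fold) completed the largest rises. The largest falls were in Ccn2 (-4.78, SE 0.14), a matrix-associated YAP target, Phlda1 (-3.99, SE 0.11), Ccn1 (-3.26, SE 0.16, with 1 of 2 forskolin arrays above background), Tnfaip3 (-3.08, SE 0.12), Lmcd1 (-3.01, SE 0.12), Fjx1 (at least 4.70-fold lower), the chemokine Ccl2 (-2.87, SE 0.13) and Ccl4 (at least 3.05-fold lower). Hdac4 rose by 1.18 (SE 0.20, adjusted p = 0.00061) and Hdac5 by 0.58 (SE 0.13, adjusted p = 0.0039), and Hdac7 fell by 2.07 (SE 0.12, adjusted p = 5.1e-08). Pcx, above background on 1 array of each group, did not pass (-0.03, adjusted p = 0.95), and Igfbp1 was below background in both groups. In all, 2481 genes passed, 1112 higher and 1369 lower.

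By list, 8 of 16 measured genes of amino acid catabolism and the urea cycle rose and 0 fell after 4 h, the same adjusted over the list alone (median 0.47, or 0.36 with genes at their bounds, adjusted p = 0.00021). Examples were the urea cycle enzyme Ass1 (1.92, SE 0.090), cystathionine synthase Cbs (2.18, SE 0.20) and the lysine-degrading Aass (1.44, SE 0.10). Slc7a2, also of this list, had no such rise against the 2 h DMSO arrays (-0.03, adjusted p = 0.88). Of 10 gluconeogenic enzymes 5 rose and 0 fell, 5 adjusted over the list alone (median 0.36, or 0.28 with bounds, adjusted p = 0.0031), but adjusted p = 0.061 with an estimated correlation. G6pc, Fbp1, Pck1 and the malate dehydrogenase Mdh1 (1.09, SE 0.22) were among the 5. Of the 17 FOXO-linked genes 9 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0063), but adjusted p = 0.074 with an estimated correlation. Glycolysis and glycogen genes, 8 higher and 1 lower of 11 on both counts including that adjusted over the list alone, passed at adjusted p = 0.019, but adjusted p = 0.11 with an estimated correlation. Cholesterol synthesis genes, 4 higher and 0 lower of 17 on both counts, passed at adjusted p = 0.031, but adjusted p = 0.15 with an estimated correlation. These last 2 lists did not pass against the 2 h DMSO arrays (adjusted p = 0.19 and 0.32).

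Several lists did not pass as a whole after 4 h in control cells. The CREB list had 8 genes higher and 4 lower (median 0.44, adjusted p = 0.13), with Nr4a2 at least 2.41-fold higher, Crem at 2.19 (SE 0.14) and Junb at -2.70 (SE 0.12). The NF-kB list had 5 higher and 11 lower (median -0.20, or -0.58 with genes at their bounds and those below background in both groups left out, adjusted p = 0.19), against 2 higher and 18 lower with the 2 h DMSO arrays (median -1.71, adjusted p = 5.1e-12). Respiratory chain genes had 4 higher and 10 lower of 24 (median -0.20, adjusted p = 0.10), among the lower Ndufa1 (-1.0, SE 0.092) and Ndufa2 (-0.96, SE 0.094). Ribosomal protein genes had 0 higher and 6 lower of 18 (median -0.22, adjusted p = 0.065), Rpl22 (-0.68, SE 0.12) and Rps16 (-0.51, SE 0.10) among them, and Rps16 lost its call against the 2 h DMSO arrays (-0.18, adjusted p = 0.18). Against those arrays the hepatocyte (adjusted p = 0.0030) and bile acid lists (0.013) passed upward, and the interferon (0.0064), p53 (0.016) and culture and cytoskeleton lists (0.030) downward. Counts adjusted over the list alone were the same for these 4 lists. Of all genes past the test 44.8% were higher, against 39.4% with median scaling of the arrays.

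The forskolin effect itself changed between 2 h and 4 h in control cells for 2061 genes, 975 in the upward and 1086 in the downward direction (interaction of treatment and time, median SE 0.19). The upward share was 47.3%, against 41% with median scaling of the arrays. Upward, the effect on Cxcl5 differed by 7.48 (SE 0.24), on Vnn3 by 4.50, on Slc7a2 by 4.35, on Cxcl1 by 4.30 and on Fbp1 by 2.37 (SE 0.19), and that on G6pc by 1.67 (SE 0.20, adjusted p = 5.2e-05). Downward, Junb, a subunit of the AP-1 factor, differed by -4.74, Lmcd1 by -3.66, Klf4 by -3.45, C2cd4a by -3.45, Hdac7 by -1.92, Pck1 by -1.67 (SE 0.28, adjusted p = 0.00073) and Igfbp1 by -2.10 (SE 0.42, adjusted p = 0.0028). Where groups lay below background, as 1 of the 4 did for Pcx, 2 for G6pc, Pck1 and Ppargc1a and 3 for Cxcl5, C2cd4a and Igfbp1, the fitted value depends on the background level. The DMSO arrays moved with these genes, since Cxcl1 fell by 2.98 and Junb rose by 1.26 under DMSO from 2 h to 4 h in control cells. Ppargc1a (-0.14, adjusted p = 0.71) and Pcx (0.50, adjusted p = 0.30) did not pass, and Pcx passed without GFP forskolin 4 h array A (0.94, adjusted p = 0.021, range 0.021 to 0.92). Hdac4 passed narrowly (0.85, SE 0.28, adjusted p = 0.042). It lost its call without any 1 of 11 arrays (any control array but forskolin 2 h B, either shHDAC45 DMSO 2 h array or either shHDAC45 forskolin 4 h array). Of these, GFP forskolin 2 h array A moved it most (0.57, adjusted p = 0.16). The call was also lost with no filter on dim probes (adjusted p = 0.077). Its adjusted p ran from 0.0064 to 0.16 over all alternatives. Hdac5 did not pass (-0.48, adjusted p = 0.070), but did without background correction (0.031), with the authors' normalized values (0.036), without GFP DMSO 2 h array B (0.041) and without GFP DMSO 4 h array A (0.047), in a range of 0.031 to 0.24. Of the genes higher at 2 h and at 4 h, 266 were shared where 117 would be if the lists were independent, and of the lower genes 260 where 147 would be. A further 206 were higher at 2 h and lower at 4 h and 83 the reverse.

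In knockdown cells after 2 h of forskolin, Sik1 was at least 6.16-fold higher, Nr4a2 at least 7.51-fold, C2cd4a at least 4.09-fold, Usp2 at least 3.44-fold, Phyhipl at least 2.06-fold and the AP-1 gene Fosl2 by 2.42 (SE 0.12). G6pc rose at least 3.83-fold (adjusted p = 1.4e-07) and Ppargc1a at least 1.56-fold (adjusted p = 1.6e-05), while Pck1 stayed below background in both groups. Crem rose by 3.28 (SE 0.14), while its other probe was not above background in either group. Ccn1 was at least 7.48-fold lower, Cxcl2 at least 3.09-fold and Ccl4 at least 2.24-fold, while the other probe of Ccl4 was not above background in either group and did not pass (adjusted p = 0.053). Cxcl5 (-3.18, SE 0.17), Cxcl1 (-3.17, SE 0.12), Ccl2 (-2.48, SE 0.13), Tnfaip3 (-2.36, SE 0.12) and the acute phase gene Saa3 (-2.36, SE 0.15) fell. Hdac5 was at least 1.2-fold higher (adjusted p = 0.00047), while its other probe was not above background in either group (adjusted p = 0.73). Hdac7 (-0.20, adjusted p = 0.44), Fbp1 (-0.12, adjusted p = 0.75) and Pcx (-0.23, adjusted p = 0.71, with 1 of 2 forskolin arrays above background) did not pass. Neither did Hdac4 (adjusted p = 0.18), for which no fold can be given, as it lay below background under DMSO. Igfbp1 rose by 1.5 (SE 0.30, adjusted p = 0.0099). The call was lost without shHDAC45 DMSO 2 h array B (1.12, adjusted p = 0.12), without shHDAC45 forskolin 2 h array A (1.28, adjusted p = 0.11) and with only the compared arrays (adjusted p = 0.057), in a range of 9.8e-05 to 0.12. In all, 372 genes passed, 177 higher and 195 lower. The count was 190 and 237 without shHDAC45 forskolin 2 h array A or B, 223 and 229 without 1 of the shHDAC45 DMSO 2 h arrays, 183 with only the compared arrays and 1578 against the DMSO arrays of 4 h.

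After 4 h of forskolin in knockdown cells, Ppargc1a was at least 2.80-fold higher (adjusted p = 1.3e-07), Igfbp1 rose by 2.01 (SE 0.30, adjusted p = 0.00023) and Fbp1 by 1.49 (SE 0.14, adjusted p = 4.1e-06). G6pc was at least 1.26-fold higher (adjusted p = 7e-04). Pck1 lay below background in both groups. The largest rises were in the nuclear receptor Rorb, at least 8.97-fold, the FGF21 coreceptor Klb, at least 4.09-fold, the G-protein regulator Rgs17, at least 3.99-fold, the keratin Krt23 (3.0, SE 0.19), the cytokine Il33 (2.95, SE 0.10), Adh1 (2.88, SE 0.15) and the decarboxylase Ddc (2.86, SE 0.18, with 1 of 2 DMSO arrays above background). The largest falls were in the cytokine Csf2, at least 9.38-fold, tissue factor F3 (-3.15, SE 0.20), Ankrd1 (-3.00, SE 0.14), Ccn2 (-2.79, SE 0.14), Fjx1 (at least 3.82-fold), Ccl3 (-2.52, SE 0.13), Ccl4 (-2.43, SE 0.17) and Ccn1 (-2.41, SE 0.16). Against the DMSO arrays of 2 h, Ccl3 (1.10, adjusted p = 3.9e-05) and Ccl4 (0.66, adjusted p = 0.0074) turned to higher. Hdac7 fell by 0.79 (SE 0.12, adjusted p = 0.00024), and Hdac4, above background on 1 of 2 DMSO arrays, rose by 0.88 (SE 0.20, adjusted p = 0.0046), a call lost without shHDAC45 DMSO 4 h array A (0.55, adjusted p = 0.057, range 0.00083 to 0.057). Pcx, also above background on 1 of 2 DMSO arrays, did not pass (0.17, adjusted p = 0.61). Neither did Hdac5 (adjusted p = 0.26), which lay below background under DMSO, so that no fold can be given. In all, 2736 genes passed, 1344 higher and 1392 lower. The share of higher genes was 49.1%, against 41.8% with median scaling. Of the genes higher in knockdown cells 127 of 177 at 2 h and 578 of 1344 at 4 h were also higher in control cells, where 18.7 and 193 would be if the lists were independent. For lower genes the numbers were 140 of 195 and 836 of 1392, where 21 and 246 would be.

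At 2 h the forskolin effect on G6pc, Pck1 and Ppargc1a was smaller in knockdown cells than in control cells. That on G6pc was lower by a log2 difference of -2.45 (SE 0.20, adjusted p = 7.5e-06), on Pck1 by -2.74 (SE 0.28, adjusted p = 6e-05) and on Ppargc1a by -1.38 (SE 0.25, adjusted p = 0.0046). Hey1 (-4.37, SE 0.15), Junb (-2.56, SE 0.17), Pde4d (-2.33, SE 0.26), Atf3 (-1.77, SE 0.19) and Nr4a2 (-1.67, SE 0.13) also had smaller effects. So did Sgk1 (-2.52, SE 0.16), Etnppl (-3.15, SE 0.25), Mmd2 (-2.34, SE 0.21) and the glycogen-targeting phosphatase subunit Ppp1r3c (-2.44, SE 0.15). The effect was less negative or more positive for Cxcl5 (4.31, SE 0.24), Cxcl1 (3.85, SE 0.17), the cytokine Il1b (3.23, SE 0.17), Ccl7 (2.99, SE 0.15), Vnn3 (2.74, SE 0.17), Tnfaip3 (2.42, SE 0.17) and lymphotoxin Ltb (2.36, SE 0.27). The G-protein regulator Rgs4 stood at 2.72 (SE 0.21). In this interaction 462 genes passed, 242 upward and 220 downward, but 300 with only the compared arrays and 775 with the DMSO arrays of 4 h. Between 1 and 3 of the 4 groups lay below background for G6pc, Pck1, Ppargc1a, Nr4a2, Etnppl, Mmd2, Hey1, Pde4d, Cxcl5, Il1b, Rgs4, Tnfaip3, Ltb, Hdac4, Hdac5, Pcx and Igfbp1, and the fitted values then depend on the background level. The differences for Hdac4 (0.21, adjusted p = 0.74), Hdac5 (-0.10, adjusted p = 0.81), Hdac7 (-0.05, adjusted p = 0.92), Fbp1 (0.14, adjusted p = 0.74), Pcx (0.30, adjusted p = 0.68) and Igfbp1 (-0.41, adjusted p = 0.64) did not pass. Hdac5 passed without background correction (-0.54, adjusted p = 0.024, range 0.024 to 0.99).

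The CREB list had the smaller effect as a group at 2 h, with 0 of 16 genes upward and 10 downward, 11 adjusted over the list alone (median -1.32, adjusted p = 5.1e-12). Its median of knockdown minus control cells was -0.72 under forskolin at 2 h, but 0.54 under DMSO at 2 h and 0.41 at 4 h. The higher DMSO level thus enters this difference with either set of DMSO arrays. The NF-kB list went upward, 13 genes against 1, and 17 against 1 adjusted over the list alone (median 1.06, adjusted p = 9.3e-18). So did the interferon list, 5 of 14 and 6 adjusted over the list alone, with 0 downward (median 0.36, adjusted p = 3.3e-05). Examples of the latter were Parp14 (1.16, SE 0.17) and Gbp3 (0.98, SE 0.18). These 3 lists also passed with an estimated correlation, with adjusted p = 0.0015, 0.00054 and 0.021. Of 12 macrophage markers 3 were upward, 4 adjusted over the list alone, and 0 downward (adjusted p = 0.044), but adjusted p = 0.15 with an estimated correlation. Of the 16 hepatocyte genes 3 were downward, 4 adjusted over the list alone, and 0 upward (adjusted p = 0.031), but adjusted p = 0.15 with an estimated correlation. The gluconeogenic list had 2 genes downward, also adjusted over the list alone, and did not pass (median 0.03, mean -0.46, test downward, adjusted p = 0.19). Under DMSO, from 2 h to 4 h, 16 of the 23 NF-kB genes rose in knockdown cells (median 1.02), where 18 fell in control cells. With the DMSO arrays of 4 h in place of those of 2 h, the CREB list stayed downward (median -0.91, adjusted p = 1.1e-09). The NF-kB list then turned downward (0 upward, 14 downward, median -1.06, adjusted p = 1.1e-21) and 3 lists changed direction and lost their calls. These were the interferon list (0 upward, 1 downward, median -0.15, adjusted p = 0.30), the macrophage list (1 and 4, median -0.25, adjusted p = 0.16) and the hepatocyte list (5 and 1, median 0.24, adjusted p = 0.057), while fatty acid oxidation (0.0016) and bile acid genes (0.042) passed upward. In that setting Cxcl5 turned to -5.37, Cxcl1 to -0.71, Il1b to -3.85, Ccl7 to -2.23 and Vnn3 to -3.73. Tnfaip3 (-0.33), Parp14 (-0.10) and Gbp3 (-0.49) also turned and lost their calls, Ltb lay below background in all 4 groups and lost its call, and Rgs4 (0.24, adjusted p = 0.53) and Ppargc1a (-0.82, adjusted p = 0.054) lost theirs. Groups again lay below background for Cxcl5, Il1b, Tnfaip3, Rgs4 and Ppargc1a. Under every other alternative run these genes kept their direction and call.

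At 4 h the difference for G6pc was larger, with a forskolin effect lower in knockdown cells by -5.76 (SE 0.20, adjusted p = 4.3e-09), and Pck1 differed by -1.61 (SE 0.28, adjusted p = 0.0029). The effect was also lower in knockdown cells for Etnppl (-4.71, SE 0.25), the cytokine Csf2 (-4.03, SE 0.16), Cyp17a1 (-3.76, SE 0.18), Sgk1 (-3.09, SE 0.16), Mmd2 (-2.99, SE 0.21), Tuba8 (-2.84, SE 0.13) and Egln3 (-2.79, SE 0.18). For Csf2, which forskolin lowered in knockdown cells, this means a more negative effect there, not a weaker rise. The effect was more positive or less negative for Phlda1 (3.60, SE 0.15), the ERK phosphatase Dusp6 (2.84, SE 0.17), Cxcl1 (2.81, SE 0.17), Olfml2b (2.54, SE 0.21), Rgs4 (2.52, SE 0.21), Plet1 (2.51, SE 0.38), Foxq1 (2.47, SE 0.19) and Cables1 (2.40, SE 0.18). It was so too for Igfbp1 (2.19, SE 0.42, adjusted p = 0.0061) and Hdac7 (1.28, SE 0.17, adjusted p = 4e-04). The other probe of Dusp6, not above background in control cells, did not pass (adjusted p = 0.071). Groups lay below background for G6pc, Pck1, Etnppl, Csf2, Cyp17a1, Mmd2, Tuba8, Plet1, Rgs4, Igfbp1, Hdac5 and Ppargc1a, and their fitted values depend on the background level. With the DMSO arrays of 2 h, Csf2 (below background in all 4 groups, adjusted p = 0.27), Egln3 (-0.34, adjusted p = 0.18) and Igfbp1 (0.82, adjusted p = 0.18) lost their calls, which they kept under every other alternative run. Hdac4 (-0.30, adjusted p = 0.58), Hdac5 (-0.38, adjusted p = 0.23), Pcx (0.20, adjusted p = 0.77), Ppargc1a (-0.19, adjusted p = 0.70) and Fbp1 (-0.62, SE 0.19, adjusted p = 0.065) did not pass. Fbp1 passed without background correction (0.0014), with the authors' normalized values (0.0075), among probes detected on all arrays (0.047) and without either shHDAC45 DMSO 2 h array (0.025), in a range of 0.0014 to 0.99, and Ppargc1a with the DMSO arrays of 2 h (0.041, range 0.041 to 1). In all, 664 genes passed, 372 upward and 292 downward, but 418 without GFP DMSO 4 h array A, 431 and 439 without shHDAC45 forskolin 4 h array A or B, and 1923 with the DMSO arrays of 2 h.

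Lists differed less clearly at 4 h, since each of the 3 that passed lost its call with an estimated correlation. The gluconeogenic list had 0 genes upward and 2 downward, G6pc and Pck1, with 3 adjusted over the list alone (median -0.13, adjusted p = 0.042, and adjusted p = 0.15 with an estimated correlation). The amino acid list had 2 downward on both counts including that adjusted over the list alone, Ass1 (-2.12, SE 0.13) and Slc7a2 (-1.70, SE 0.17), and 0 upward (median -0.16, adjusted p = 0.029, and adjusted p = 0.15 with an estimated correlation). The NF-kB list had 8 upward and 2 downward, 9 and 3 adjusted over the list alone (median 0.13, adjusted p = 0.011, and adjusted p = 0.074 with an estimated correlation). Tnfaip3 (2.16, SE 0.17) and Ccl2 (1.81, SE 0.18) were among its upward genes. With the DMSO arrays of 2 h the first 2 lists did not pass (adjusted p = 0.083 and 0.18), Slc7a2 turned to 2.95 and 22 NF-kB genes were upward (median 2.69, adjusted p = 6.4e-28). The hepatocyte list then passed downward (1 upward, 9 downward, median -0.61, adjusted p = 0.0016) and the interferon list, whose median turned from -0.24 to 0.30, upward (5 and 0, adjusted p = 0.035). The CREB list did not pass (5 upward and 2 downward, or 5 and 3 adjusted over the list alone, median 0.22, adjusted p = 0.097), with Ier3 (2.06, SE 0.16) and Junb (1.55, SE 0.17) upward. Averaged over both times, 842 genes had a different forskolin effect, 456 upward and 386 downward. G6pc (-4.11, SE 0.14), Etnppl (-3.93, SE 0.18), Hey1 (-2.99, SE 0.11) and Cyp17a1 (-2.82, SE 0.13) led downward, and Cxcl1 (3.33, SE 0.12), Rgs4 (2.62, SE 0.15), Tnfaip3 (2.29, SE 0.12) and Phlda1 (2.22, SE 0.11) upward. Of these, Cxcl1 and Phlda1 were above background in all 8 groups, and the fitted values of the others depend on the background level.

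Over all forskolin-responsive genes the response at 2 h was smaller in knockdown cells. Across the 1581 genes called by the mean forskolin effect of both viruses, the slope of the knockdown effect on the control effect was 0.440 (limma fry on the interaction, adjusted p = 1.8e-10 over the 2 times). It was 0.467 for the 746 rising and 0.416 for the 835 falling genes. The effect was smaller for 1303 of them (82.4%), and of 351 genes whose difference passed the test 337 had the smaller effect in knockdown cells. With the 4 h DMSO arrays the slope was 0.635 and the fry test passed in the other direction. At 4 h the slope was 0.686 over 3577 genes and the fry test did not pass (adjusted p = 0.43). The effect was smaller for 1667 of them (46.6%), and of 486 differences past the test 275 were smaller and 211 larger. That test passed without GFP DMSO 4 h array B (slope 0.669), without GFP forskolin 4 h array A (0.673) and with the 2 h DMSO arrays (0.421). An orthogonal slope, which treats both axes alike and was added after seeing the data, was 0.482 at 2 h and 0.893 at 4 h. The effects in the 2 viruses correlated across genes, which are not independent replicates, at r = 0.803 (rho = 0.745) at 2 h and r = 0.746 (rho = 0.770) at 4 h.

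**Figure D3:**
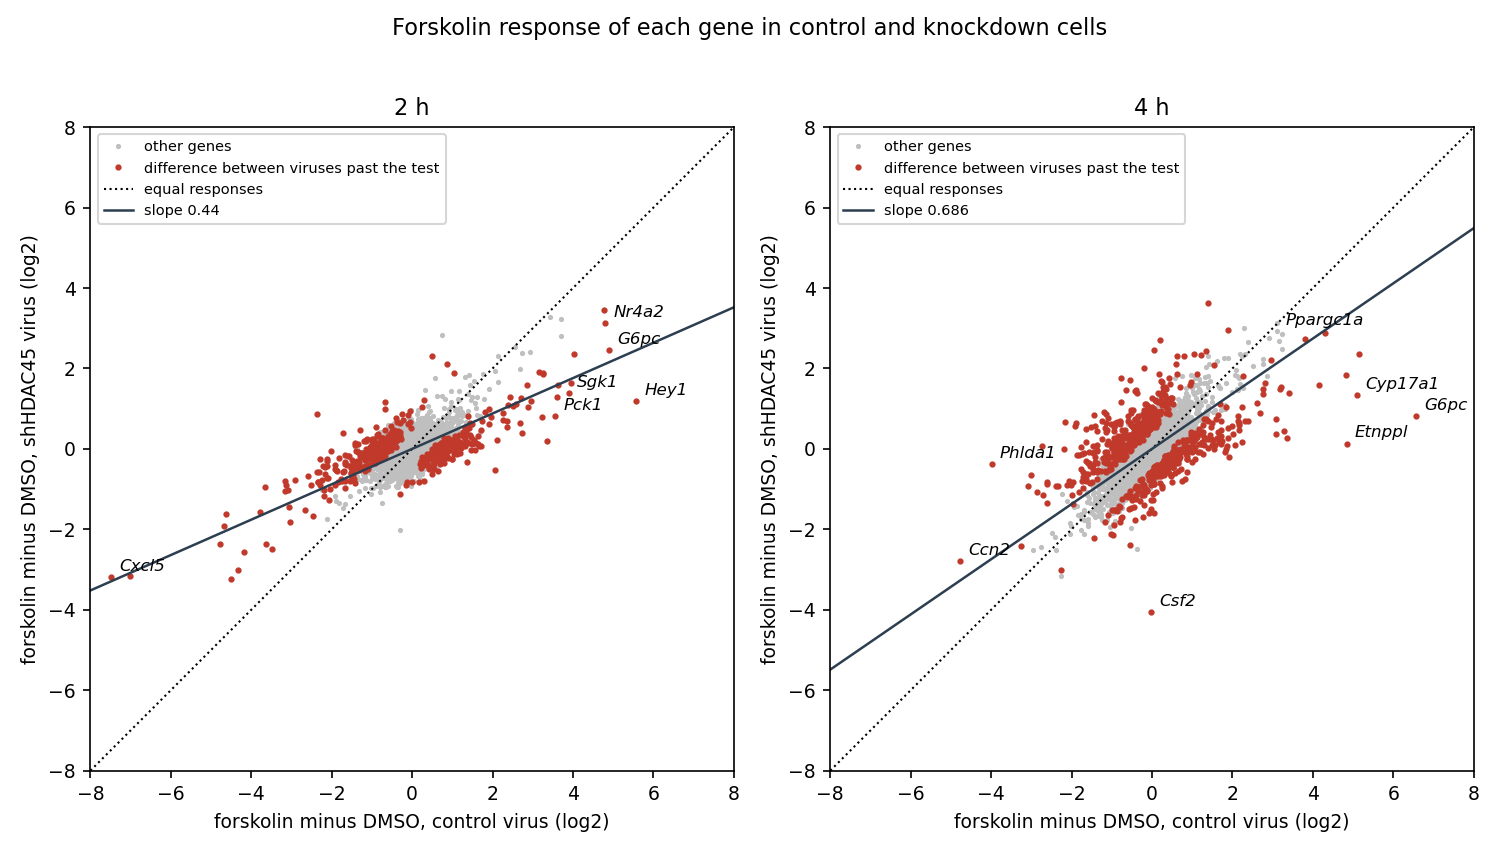
Log2 fold change of forskolin over DMSO in control cells (horizontal) and knockdown cells (vertical) for the tested genes, at 2 h and at 4 h, with genes whose difference passed the test in red and the fitted slope through the origin as a line. The slope is 0.440 at 2 h and 0.686 at 4 h.

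Knockdown and control cells were also compared within each condition. These cells differ by the whole virus, so a loss of Hdac4 and Hdac5 cannot be told apart from other effects of the virus. Under DMSO at 2 h 3876 genes passed, with Tnnt2 (4.45, SE 0.15), the cell cycle factor E2f2 (at least 7.42-fold) and Igfbp1 (at least 3.07-fold) higher and the iron hormone gene Hamp (-3.80, SE 0.16) and the acute phase gene Crp (-3.49, SE 0.12) lower. Under DMSO at 4 h 4083 passed, with the inflammatory genes Cxcl5 (at least 40.8-fold), Cxcl2 (at least 16.5-fold), Saa3 (5.40, SE 0.15) and Il1b (at least 7.31-fold) and Igfbp1 (at least 1.45-fold) higher. Under forskolin at 2 h 3877 passed, with G6pc 5.54-fold lower (log2 -2.47, SE 0.14), Pck1 at least 4.22-fold and the sulfotransferase Sult1a1 at least 6.04-fold lower, Ppargc1a lower (-1.19, SE 0.17) and E2f2 (at least 6.85-fold) and Igfbp1 (2.42, SE 0.30) higher. Under forskolin at 4 h 4576 passed, with G6pc 63.3-fold lower (log2 -5.98, SE 0.14, adjusted p = 8.9e-12), Etnppl at least 16.7-fold, Pck1 at least 1.74-fold and the P450 gene Cyp1a2 (-4.52, SE 0.13, with 1 of 2 knockdown arrays above background) lower. Higher in that condition were Cxcl1 (7.13, SE 0.12), Cxcl5 (at least 30.7-fold) and Igfbp1 (at least 6.41-fold). Ppargc1a was lower in this last condition (-0.56, adjusted p = 0.014), but not without GFP forskolin 4 h array B (-0.48, adjusted p = 0.085) or without shHDAC45 forskolin 4 h array A (-0.54, adjusted p = 0.062). Its range was 0.0011 to 0.085. Fbp1 was lower in each of the 4 conditions, by log2 differences of -1.41, -0.79, -1.26 and -1.41 in the order given. Hdac7 was lower in 3 (-0.83, -1.22 and -0.88) and not under forskolin at 4 h (0.06, adjusted p = 0.67). Pcx passed in none, with -0.36 and 0.03 under DMSO, no fold under forskolin at 2 h, where control cells lay below background, and 0.22 under forskolin at 4 h. At 4 h it was above background on 1 of 2 arrays in each group but knockdown cells under forskolin. It passed under DMSO at 2 h with only the compared arrays (adjusted p = 0.038, range 0.038 to 0.45) and under forskolin at 4 h without GFP forskolin 4 h array B (0.67, adjusted p = 0.014, range 0.014 to 0.97). Between DMSO and forskolin at 2 h the lists of higher genes shared 1429 where 493 would be shared if they were independent, and the lists of lower genes 1354 where 477 would be. At 4 h these were 1648 where 618 would be and 1565 where 588 would be.

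Averaged over the 4 conditions, the cell cycle list was higher (18 of 18 genes, adjusted p = 4.3e-09) and the hepatocyte list lower (14 of 16 genes, adjusted p = 1.3e-05) in knockdown cells. The matrix metalloproteinases Mmp3 (4.31, SE 0.073) and Mmp17 (3.61, SE 0.090), Nxph1 (4.01, SE 0.058), Tnnt2 (3.93, SE 0.075), the GTPase Rab15 (3.83, SE 0.081), E2f2 (3.76, SE 0.069), the interferon-inducible chemokine Cxcl10 (3.62, SE 0.081) and the fetal growth factor Igf2 (3.56, SE 0.076) had the largest fitted rises. Sult1a1 (-3.75, SE 0.063), vitronectin Vtn (-3.59, SE 0.047), Cyp1a2 (-3.23, SE 0.063), the plasmin inhibitor Serpinf2 (-3.14, SE 0.065) and the antitrypsin genes Serpina1a (-3.33, SE 0.12), Serpina1d (-3.20, SE 0.064) and Serpina1b (-3.17, SE 0.065) had the largest falls beside Hdac5. Other detected probes gave smaller falls for Serpinf2 (-1.48) and Hdac5 (-2.15) and larger ones for Serpina1a (-3.50) and Serpina1b (-3.83). The antitrypsin genes are near-identical copies whose probes may share transcripts, so their values are uncertain as separate genes. Among fixed genes, G6pc (-2.17, SE 0.069), Fbp1 (-1.22, SE 0.068), Pck1 (-1.10, SE 0.098) and Ppargc1a (-0.48, SE 0.087, adjusted p = 0.00022) were lower and Igfbp1 (2.58, SE 0.15) higher, and Pcx (-0.04, adjusted p = 0.75) did not pass. In 4 of the 8 groups Mmp3, Mmp17, Nxph1, Rab15, E2f2, Cxcl10, Igf2, Sult1a1, G6pc and Ppargc1a lay below background, as did Pck1 in 6, Cyp1a2 and Igfbp1 in 3 and Tnnt2 and Pcx in 1, and those fitted values depend on the background level. In all, 5712 genes passed, 2906 higher and 2806 lower, with a median SE of 0.067. Of these 4570 had the same sign in all 4 conditions, and 2075 passed in each of them, 1066 higher and 1009 lower.

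By list, all 18 measured cell cycle genes were higher in knockdown cells, also adjusted over the list alone (median 1.46, adjusted p = 4.3e-09). Among them were the cyclins Ccne1 (3.56, SE 0.062) and Ccne2 (3.43, SE 0.088), the ribonucleotide reductase subunit Rrm2 (2.59, SE 0.066) and the kinase Cdk1 (1.90, SE 0.047). Of 16 hepatocyte genes 14 were lower and 1 higher, 15 and 1 adjusted over the list alone (median -1.12, adjusted p = 1.3e-05), with Cyp2c37 (-3.00, SE 0.056), Apoe (-2.09, SE 0.054) and Hnf4a (-1.96, SE 0.059) among them. These 2 lists also passed with an estimated correlation (adjusted p = 0.0032 and 0.022). Of 20 unfolded protein and amino acid response genes 15 were higher and 2 lower, also adjusted over the list alone (median 0.59, adjusted p = 0.0076), but adjusted p = 0.091 with an estimated correlation. The cystine transporter Slc7a11 (2.10, SE 0.088), Ddit4 (1.88, SE 0.10) and Trib3 (0.86, SE 0.057) were examples. Of the 23 NF-kB genes 15 were higher and 7 lower, also adjusted over the list alone (median 1.25, adjusted p = 0.029), but adjusted p = 0.11 with an estimated correlation. Cxcl1 (3.70, SE 0.058), Cxcl5 (3.16, SE 0.084) and Cxcl2 (2.36, SE 0.064) rose and Crp (-2.26, SE 0.060) fell. This list was mostly lower under DMSO at 2 h (2 higher, 16 lower) and mostly higher under DMSO at 4 h (18 higher, 2 lower). Of 8 bile acid genes 7 were lower and 1 higher, also adjusted over the list alone (median -0.89, adjusted p = 0.017), but adjusted p = 0.18 with an estimated correlation. The bile acid receptor Nr1h4 (-1.60, SE 0.054), the phospholipid exporter Abcb4 (-0.96, SE 0.058) and the hydroxylase Cyp7b1 (-0.95, SE 0.092) were lower. Groups lay below background for Ccne2, Cyp2c37, Slc7a11, Cxcl5 and Cxcl2, and their fitted values depend on the background level.

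Markers of other liver cell types moved in different directions in the knockdown. Of 11 endothelial markers 10 were higher and 0 lower, also adjusted over the list alone (median 0.46, adjusted p = 0.025), but adjusted p = 0.18 with an estimated correlation. Flt1 (1.38, SE 0.053), Lyve1 (0.80, SE 0.078), Esam (0.80, SE 0.057) and Cdh5 (0.61, SE 0.057) were among them. Of 10 stellate and fibroblast markers 8 were higher and 0 lower (median 0.59), including Col3a1 (1.14, SE 0.16), Timp1 (0.89, SE 0.053) and Dcn (0.65, SE 0.064), though the list did not pass (adjusted p = 0.050). Of 12 macrophage markers 2 were higher and 7 lower (median -0.25, adjusted p = 0.29), with Vsig4 (-1.21, SE 0.054) and C1qa (-0.62, SE 0.061) lower and Cd14 (0.96, SE 0.048) higher. Of 6 bile duct markers 4 were lower and 1 higher (median -1.12, adjusted p = 0.13), with Sox9 (-1.98, SE 0.051), Prom1 (-1.78, SE 0.059) and Krt19 (-1.76, SE 0.11) lower and Cldn7, below background in 6 groups, higher. The fitted values of Flt1, Col3a1, Krt19 and Cldn7 depend on the background level. For the last 3 of these lists the counts adjusted over the list alone were the same.

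The gluconeogenic, fatty acid oxidation, amino acid, cholesterol synthesis and oxidative and xenobiotic lists did not pass as a whole in the knockdown, although most of their members with a call were lower. Of 10 gluconeogenic enzymes 5 were lower and 2 higher (median -0.60, adjusted p = 0.16) and of 10 fatty acid oxidation genes 6 and 1 (median -0.53, adjusted p = 0.079). Of 16 amino acid genes 11 were lower and 4 higher (median -0.27, adjusted p = 0.15), of 17 cholesterol synthesis genes 8 and 1 (median -0.14, adjusted p = 0.15) and of 18 oxidative and xenobiotic genes 11 and 4 (median -0.43, adjusted p = 0.14). The glycerol phosphate dehydrogenase Gpd1 (-2.27, SE 0.051), the acyl-CoA dehydrogenase Acadl (-1.54, SE 0.073) and the glutathione transferases Gstm1 (-2.51, SE 0.072) and Gsta1 (-2.02, SE 0.061) were among the lower genes. Circadian clock genes (2 higher, 5 lower, adjusted p = 0.097), FOXO-linked genes (3 and 8, adjusted p = 0.32), CREB-linked genes (7 and 4, adjusted p = 0.29) and class IIa deacetylases with their partners (2 and 4, adjusted p = 0.29) did not pass. Neither did p53 response genes (10 higher, 2 lower of 16, median 0.41, adjusted p = 0.095), culture and cytoskeleton genes (8 and 9 of 22, adjusted p = 0.67) and glycolysis and glycogen genes (6 and 4, adjusted p = 0.79). The same held for other deacetylases and sirtuins (4 and 3 of 9, adjusted p = 0.93), respiratory chain genes (8 and 4, adjusted p = 0.96) and ribosomal protein genes (3 and 3, adjusted p = 0.93). Fatty acid synthesis genes (7 and 6 of 14, adjusted p = 0.81) had a median of 0.10 and a mean of -0.13. Interferon genes (6 and 7, adjusted p = 0.93) had a median of -0.15 and a mean of 0.14, with both tests pointing down. Respiratory chain genes had a median of 0.0040 and a mean of -0.0040, with the test pointing up. Adjusted over the list alone these counts were the same, except that 6 respiratory chain genes were higher. In total 130 tests of lists were adjusted together, 27 passed, and 9 of these also passed with an estimated correlation.

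**Figure D4:**
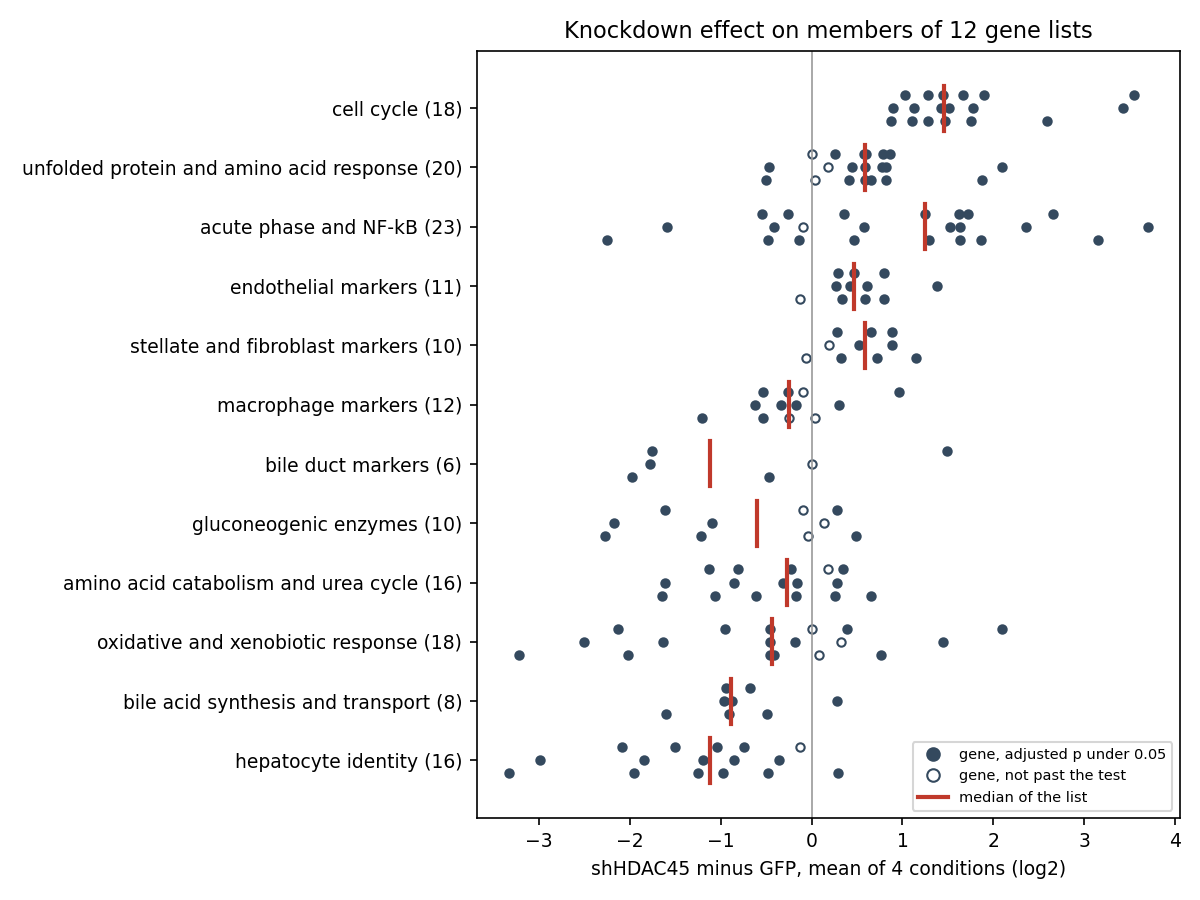
Log2 fold change of knockdown over control cells, averaged over the 4 conditions, for the measured members of 12 gene lists, with filled points past the test and the median of each list in red. The 18 cell cycle genes lie above 0 and 14 of the 16 hepatocyte genes were lower past the test.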

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

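In this part the tests on cell types, exchanged labels, cultures, cell cycle phases and dim probes were chosen only after the result was seen; the counts over other splits of the arrays were planned. Fitted differences of genes with groups below background, named with those genes above, depend on the background level. In this part the SE of a list median is the SD of medians over resampled genes of the list. It treats the genes as independent and does not measure the spread between arrays or cultures.

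The forskolin effect in control cells differed between 2 h and 4 h in the interaction test for 2061 genes. Among named genes the log2 difference was 7.48 for Cxcl5, 4.50 for Vnn3, 4.35 for Slc7a2, 4.30 for Cxcl1, 2.37 for Fbp1, 1.67 for G6pc and 0.85 for Hdac4. It was -4.74 for Junb, -3.66 for Lmcd1, -3.45 for both Klf4 and C2cd4a, -2.10 for Igfbp1, -1.92 for Hdac7 and -1.67 for Pck1.

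The forskolin effect at 2 h differed between knockdown and control cells for 462 genes, with a slope of 0.440. Downward stood Hey1 (-4.37), Etnppl (-3.15), Pck1 (-2.74), Junb (-2.56), Sgk1 (-2.52), G6pc (-2.45), Ppp1r3c (-2.44), Mmd2 (-2.34), Pde4d (-2.33), Atf3 (-1.77), Nr4a2 (-1.67) and Ppargc1a (-1.38). Upward stood Cxcl5 (4.31), Cxcl1 (3.85), Il1b (3.23), Ccl7 (2.99), Vnn3 (2.74), Rgs4 (2.72), Tnfaip3 (2.42), Ltb (2.36), Parp14 (1.16) and Gbp3 (0.98). List medians were -1.32 for CREB-linked genes, 1.06 for NF-kB genes, 0.36 for interferon genes, 0.12 for macrophage markers and -0.11 for hepatocyte genes. With the DMSO arrays of 4 h all of these upward genes but Rgs4 changed direction, and Rgs4 and Ppargc1a lost their calls. The test of the slope and the NF-kB list then turned as well. The interferon, macrophage and hepatocyte lists turned and lost their calls, while the CREB list stayed downward.

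At 4 h the effect differed between the viruses for 664 genes. Downward stood G6pc (-5.76), Etnppl (-4.71), Csf2 (-4.03), Cyp17a1 (-3.76), Sgk1 (-3.09), Mmd2 (-2.99), Tuba8 (-2.84), Egln3 (-2.79), Ass1 (-2.12), Slc7a2 (-1.70) and Pck1 (-1.61). Upward stood Phlda1 (3.60), Dusp6 (2.84), Cxcl1 (2.81), Olfml2b (2.54), Rgs4 (2.52), Plet1 (2.51), Foxq1 (2.47), Cables1 (2.40), Igfbp1 (2.19), Tnfaip3 (2.16), Ier3 (2.06), Ccl2 (1.81), Junb (1.55) and Hdac7 (1.28). List medians were -0.13 for gluconeogenic enzymes, -0.16 for amino acid genes and 0.13 for NF-kB genes. With the DMSO arrays of 2 h Slc7a2 turned upward, and Csf2, Egln3 and Igfbp1 lost their calls. The gluconeogenic and amino acid lists then did not pass.

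Averaged over both times the effect differed for 842 genes, with Cxcl1 at 3.33, Rgs4 at 2.62, Tnfaip3 at 2.29, Phlda1 at 2.22, G6pc at -4.11, Etnppl at -3.93, Hey1 at -2.99 and Cyp17a1 at -2.82. Of 100 splits of the arrays between viruses within each condition 7, the real one included, gave as many genes, the highest other giving 5712. All 6 others as large carry part of the difference between the viruses into the interaction, a structure of the samples, so these splits say nothing on chance for this count.

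Among detected probes that name no single gene, which entered no comparison above, 776 of 1131 differed between knockdown and control cells, 395 higher and 381 lower. Of the named genes tested, 5712 of 7746 (73.7%) did, so such a difference was not particular to these probes.

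Genes of the acute phase and NF-kB list, chemokines included, mostly fell from 2 h to 4 h under DMSO in control cells (median -1.40, SE 0.21). In knockdown cells 16 of the 23 rose, 0 fell and 7 did not pass. Among these 7 were Icam1 (-0.22, limma adjusted p = 0.21), Relb (0.14, 0.74) and Nfkb2 (0.18, 0.72), which fell in control cells. The list median of the difference of forskolin effects between the viruses at 2 h turned from 1.06 to -1.06 with the DMSO arrays of 4 h. More macrophages in the wells with high levels are argued against as the whole cause in control cells, where macrophage markers without Cd14 had a median of -0.0536 (SE 0.24), although 4 of the 12 markers, Cd14 included, fell and 2 rose, but stay open in knockdown cells, where that median was 0.371 (SE 0.25) and 4 of the 12 rose and 1 fell, beside 1.02 (SE 0.31) for the NF-kB genes. Exchanged labels between control and knockdown arrays are argued against too, because the lowest control array under DMSO lay 3.19 above the highest knockdown array for Hdac5. Exchanged labels of the 2 h and 4 h DMSO arrays within a virus were not tested. Hdac5 could not show them, as it did not differ by the test between these times in control cells (-0.040) and lay below background at both times in knockdown cells. Cultures that differed by chance, each group being 1 culture arrayed 2 times, cannot be told apart from an effect of time and virus, as the arrays of every group correlated at 0.992 or more and the sources used here name no separate cultures. A response of the cells to plating, virus or solvent that runs at a different pace in knockdown cells may also lie behind the pattern and was not tested.

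Endothelial (median 0.463, SE 0.12) and stellate markers (0.589, SE 0.17) were higher in the knockdown and hepatocyte genes lower (-1.12, SE 0.27). A lower share of hepatocytes with all other types raised alike would also raise macrophage and bile duct markers. Their medians were -0.255 (SE 0.13) and -1.12 (SE 0.75, over 6 genes). By condition the macrophage median ran from -0.42 under DMSO at 2 h to -0.0018 under DMSO at 4 h, so it was not clearly below 0 in each. These values weigh only against such an even rise, and neither list passed the test as a whole. As the other types need not rise alike, a lower share of hepatocytes is not excluded. A higher share of endothelial or stellate cells stays open, as does a change of these genes within hepatocytes through the knockdown or another effect of its virus. None of these was tested. For the knockdown difference as a whole, with 5712 genes, 1 of 100 splits of the arrays gave as many, the real one, and the highest other gave 4463, or 661 among splits that break up groups. As the arrays of a group may be technical repeats and only 3 other splits keep groups whole, these splits are too few to judge chance between cultures.

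All measured cell cycle genes were higher in the knockdown, with a median of 1.46. Other genes of like mean level did not share this rise in the normalized values. That median stood at percentile 100 of 10000 lists matched on mean level, whose medians centred on -0.00745 and reached 0.594. Quantile normalization evens out a common rise of dim probes beforehand, so this comparison cannot judge a higher intensity of all dim probes in the signals before it. Dividing cells of another type cannot be told apart from a change in hepatocytes. Genes of G1/S (median 1.72) exceeded those of G2/M (1.36) by 0.358, within an SE of 0.53. That balance of phases cannot show which cells divide, since cycling cells of either kind could raise genes of both phases. An effect of the knockdown on the hepatocytes' own cycle is a hypothesis that these data leave untested.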

How the results depend on the processing

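The DMSO arrays of the other time and the orthogonal slope were chosen only after the result was seen; all other alternatives were planned. Signal over background limits the results: 10439 of 24613 probes were above background on enough arrays, and below it only bounds can be given, so that fitted values below that involve such groups depend on the background level. Of 298 gene values, all kept direction and side of the threshold with all probes, with another variance prior and with the replicate block, as did 297 without a filter on dim probes, 297 with median scaling, 295 with the authors' values, 295 with only the compared arrays and 292 without background correction. Of the 18 main results, counts stayed within 1.5 times and slopes and targets kept their call with median scaling, no background correction, the authors' values, another variance prior and the replicate block. The slide as a block was not run, as the sources used here name no slide. Except where stated the cause was not tested.

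With an estimated correlation the count of list tests passed, out of 130 over 26 lists and 5 contrasts, went from 27 to 9. With only the compared arrays, which leaves fewer arrays to estimate the spread, counts were 1087 (forskolin in control cells, 2 h), 183 (in knockdown cells, 2 h) and 300 (difference of effects, 2 h). Without background correction Pcx turned to 0.00040 (control cells, 4 h), and at 2 h the difference of effects turned to -0.00095 for Hdac4 and 0.36 for Igfbp1. Median scaling turned Pcx to 0.029 (control cells, 4 h), and the authors' values turned Igfbp1 to 0.12 (difference, 2 h).

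With the DMSO arrays of the other time, counts were 1578 (forskolin in knockdown cells, 2 h), 775 (difference, 2 h) and 1923 (difference, 4 h), and the slope was 0.635 at 2 h, with the test turned, and 0.421 at 4 h, now past the test. Forskolin effects turned to 0.53 for Fbp1 and 0.014 for Pcx (control cells, 2 h), -0.029 for Slc7a2 (control cells, 4 h), 0.049 for Fbp1 (knockdown cells, 2 h), 1.10 for Ccl3 and 0.66 for Ccl4 (knockdown cells, 4 h). Differences of effects at 2 h turned to -5.37 for Cxcl5, -0.71 for Cxcl1, -3.85 for Il1b, -2.23 for Ccl7, -3.73 for Vnn3, -0.33 for Tnfaip3, -0.45 for Ltb, 0.34 for Hdac7, -0.48 for Fbp1, 0.97 for Igfbp1, -0.088 for Pcx, -0.096 for Parp14 and -0.49 for Gbp3, and at 4 h to 2.95 for Slc7a2. Ltb lay below background in all 4 groups of that comparison.

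Leaving out each array, 276 of 288 main values held, counts within 1.5 times and slopes and targets with their call and direction. Of 4768 gene values 4719 kept their call and direction. The count for forskolin in control cells at 2 h ran from 1041 (without GFP DMSO 2 h A) to 1654, and in knockdown cells at 2 h from 190 (without shHDAC45 forskolin 2 h A) to 370, with 237 without forskolin 2 h B and 223 and 229 without a shHDAC45 DMSO 2 h array. The difference at 4 h ran from 418 (without GFP DMSO 4 h A) to 636, with 431 and 439 without shHDAC45 forskolin 4 h A or B. The slope at 4 h ran from 0.666 to 0.695; its test passed without GFP DMSO 4 h B (0.669) and GFP forskolin 4 h A (0.673), and its direction turned without shHDAC45 DMSO 4 h A (0.695) and shHDAC45 forskolin 4 h B (0.694).

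Among gene values past no test, Pcx ran from -0.47 to 0.42 (control cells, 4 h; turned without GFP DMSO 4 h A or forskolin 4 h A), -0.064 to 0.40 (knockdown cells, 4 h; turned without shHDAC45 forskolin 4 h B), -0.19 to 0.24 (knockdown effect, DMSO 4 h; turned without GFP or shHDAC45 DMSO 4 h B). Pcx also ran from -0.23 to 0.67 (knockdown effect, forskolin 4 h; turned without GFP forskolin 4 h A or shHDAC45 forskolin 4 h B), -0.16 to 0.069 (averaged knockdown effect; turned without GFP DMSO 4 h A, GFP forskolin 4 h B or shHDAC45 forskolin 4 h A) and -0.25 to 0.64 (difference, 4 h; turned without GFP DMSO 4 h A, GFP forskolin 4 h A or shHDAC45 forskolin 4 h B). Fbp1 ran from -0.34 to 0.11 (knockdown cells, 2 h; turned without shHDAC45 DMSO 2 h A) and -0.086 to 0.37 (difference, 2 h; turned without shHDAC45 DMSO 2 h B). Ppargc1a ran from -0.33 to 0.047 (control cells, 4 h minus 2 h; turned without GFP DMSO 4 h B or forskolin 2 h B) and -0.38 to 0.0011 (difference, 4 h; turned without GFP DMSO 4 h A). Hdac7 ran from -0.085 to 0.21 (knockdown effect, forskolin 4 h; turned without GFP or shHDAC45 forskolin 4 h A) and -0.12 to 0.032 (difference, 2 h; turned without shHDAC45 DMSO 2 h B). Hdac4 ran from -0.076 to 0.50 (difference, 2 h; turned without GFP forskolin 2 h A) and -0.64 to 0.031 (difference, 4 h; turned without shHDAC45 DMSO 4 h B), and Hdac5 from -0.24 to 0.034 (difference, 2 h; turned without GFP DMSO 2 h A or forskolin 2 h A).

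The array letters were not taken to pair the samples, since not every pair of groups had deviations from the group means that correlated above 0.1. Over 28 pairs the correlation was 0.049 to 0.31 (median 0.22), with 3 at or below 0.1, all of them pairs with shHDAC45 forskolin 4 h. Arrays of the same letter thus deviated together to some degree, a hint from the data and not from the design. With the replicate block 2027 genes passed for forskolin in control cells at 2 h and 5888 for the averaged knockdown effect, and no main count moved by over 1.5 times. Of the lists, stellate and fibroblast markers in the averaged knockdown (adjusted p = 0.038, against 0.050 without it) and unfolded protein genes in the difference at 4 h (0.049, against 0.079) passed with the replicate block. With an estimated correlation they had adjusted p = 0.15 and 0.18.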

Other observations

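The comparisons of DMSO arrays between the times in this part were chosen only after the result was seen. Between the 2 h and 4 h DMSO arrays 907 genes differed in control cells and 669 in knockdown cells. Beside the chemokines, the acute phase gene Saa3 fell by 4.05 in control cells and rose by 2.11 in knockdown cells, the iron hormone gene Hamp fell by 2.86 and rose by 2.25, and Crp fell by 1.31 in control cells and did not pass in knockdown cells (0.38, adjusted p = 0.074). Il1b went from above to below background in control cells and from below to above it in knockdown cells. Of 16 hepatocyte genes 6 rose and 0 fell in control cells (median 0.22), and 2 rose and 6 fell in knockdown cells (median -0.14). Of 8 bile acid genes 4 rose in control cells and 0 in knockdown cells, and of 14 interferon genes 5 fell in control cells while 1 rose in knockdown cells. Of 18 oxidative and xenobiotic genes 4 rose in control cells and 7 in knockdown cells, with 0 lower in either. The difference between the viruses in this change over time was not tested.

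Lists that were not tested in the single knockdown conditions can be given as counts. All 18 cell cycle genes were higher in knockdown cells in each of the 4 conditions, with medians of 1.37 under DMSO at 2 h, 1.38 under DMSO at 4 h, 1.55 under forskolin at 2 h and 1.54 under forskolin at 4 h. Of 16 CREB-linked genes 9 were higher and 0 lower under DMSO at 2 h and 8 and 0 under DMSO at 4 h, with 5 below background in both viruses at either time. Under forskolin 2 were higher and 9 lower at 2 h, and 10 higher and 3 lower at 4 h. Of 23 NF-kB genes 8 were higher and 8 lower under forskolin at 2 h, and 19 higher and 2 lower at 4 h. In knockdown cells 4 h of forskolin lowered 12 of 24 respiratory chain genes and raised 5, lowered 8 of 18 ribosomal protein genes and raised 0, and raised 6 of 11 endothelial markers and lowered 0.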
